A study of Homo sapiens with 18 samples.

How the data were processed

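Total RNA was sequenced from 18 libraries of cortical brain organoids made from the wildtype KOLF2.2J line, with 3 libraries at each of days 3, 4, 5, 20, 25 and 32. Per the labels' protocols, RNA was extracted with a kit from QIAGEN or MACHEREY-NAGEL, without saying which kit served which library. Libraries were made with the KAPA RNA HyperPrep kit after depletion of ribosomal RNA and run on an Illumina NovaSeq X. Groups and replicate numbers were taken from the sample titles. The description field of every sample names an ISL1 knockout and mesoderm, and the cell type field names induced pluripotent stem cells; the titles, the model system field and the series' design text name wildtype cortical organoids, and these were followed.

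The authors deposited a table of whole-number gene counts, which was the basis of the main tests. Per the submitters' processing notes, STAR, Salmon and featureCounts were used with the genome build GRCh38; the versions, roles, strand setting and annotation release are not given in the sources used here. The authors also deposited estimated counts per gene, with fractions in one table and whole numbers in another. The whole-number version differed from the fractional one by at most 0.500 per gene and library. The estimated counts were rounded to whole numbers before they were tested, as alternatives. A further deposited table holds counts of reads per library that belong to no gene. The deposited TPM and transcript tables were not used here.

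The count table held 38592 Ensembl genes. Symbols came from a gene name table for 38568 of them, and coordinates from GENCODE release 29 (GRCh38), which held 34390 of them and may not be the authors' release. Total gene counts per library were 22886333 to 31992494. Of all reads of a library, 4.71 to 6.02% were unmapped, 6.31 to 10.2% mapped to several places, 12.1 to 19.0% fell in no gene and 3.94 to 5.09% were ambiguous, and these were left out of library sizes. Mitochondrial genes took 0.975 to 1.78% of the gene counts, and the 10 most abundant genes of a library 5.12 to 7.73%. All pairs of libraries of 1 day differed by more than sampling noise in a chi-square comparison of their counts (3.48 to 14.9 per degree of freedom), so none was treated as a copy of another.

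Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which left 21283 genes, scaled by TMM (factors 0.961 to 1.05) and fitted with 1 mean per day over all 18 libraries. The robust quasi-likelihood test compared each day with the day before it in the series, two-sided, and an F test compared all 6 days. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. Changes of at least 2-fold are counted by the estimated fold of called genes, without a test against a 2-fold change. SE values are the size of the log2 fold change divided by the root of the F statistic. The 31 gene lists, fixed before the data were examined, were tested with camera from limma 3.58.1 at a preset correlation of 0.0100, two-sided, and adjusted over the 155 tests of all lists and steps. A list described as rising or falling passed that test. CPM values are TMM-scaled, and principal components used log2 CPM with a prior count of 2.

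Genes are named by a rule fixed before the data were examined. At each step it takes the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher day, no overlap between the 3 libraries of each day, and a symbol. It takes up to 4 called members with the smallest adjusted p from each list, members that went the other way, and 13 panel genes at every day. Some genes that the rule takes are not reported here. Where a day had no counts of a gene, a fold is given as a bound against a floor of 3 counts over the 3 libraries of that day, and with 1 to 3 counts as a ratio with its exact 95% interval. Both cover counting error only, because the reads carry no molecular identifiers. Reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty. The 2 kinds of counting table differed over 2-fold in the total of 4584 genes, and a named gene among these is called uncertain. Among them was MALAT1, chosen after its values were seen, with 25725 counts against 2605709.8 estimated counts, which is not interpreted.

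The alternatives were both tables of estimated counts, DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, leaving out genes over 1% of a library, a block by replicate number, only the libraries of the compared days, a test against a 2-fold change, and leaving out each library. For lists they were camera with an estimated correlation and fry. A fit without genes that differ over 2-fold between the tables was chosen after seeing the data. The gene test was tested on simulated counts with 200 changed genes per step. For day 4 against day 3 (20992 genes) it recovered 70.1% of changes of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold, with 13 false calls. In the same simulation camera called 0 of 30 unchanged lists. Each gene was drawn independently there, so this does not test lists whose members vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.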

Results

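Cortical brain organoids were grown from KOLF2.2J, an established line of human induced pluripotent stem cells, with dorsal forebrain patterning according to the sample labels, and total RNA was sequenced after removal of ribosomal RNA. The 18 libraries covered 6 days of differentiation (days 3, 4, 5, 20, 25 and 32), with 3 libraries of the wildtype line per day. The total gene count per library ranged from 22886333 to 31992494, and 26460 to 27682 genes had at least 1 count in a library. The labels call the 3 libraries of a day biological replicates without naming separate cultures. The p-values therefore rest on the spread between libraries of a day, pooled over the 6 days, not between known separate cultures. The description field of every sample conflicts with the titles: it names a knockout of ISL1, a LIM homeodomain transcription factor of motor neurons and other lineages, and mesoderm as the target tissue. ISL1 counts were low at all days: 5 to 6 per library at day 3, 6 at day 4 and 0 to 2 at day 5. They were 5 to 32 at day 20, 3 to 5 at day 25 and 4 to 7 at day 32. These counts left ISL1 under the low-count filter, and with no other genotype in the series they do not check the label. Levels are given in CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD of n = 3 libraries.

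The first principal component of log2 CPM carried 86.1% of the variance and separated days 3 to 5 from days 20 to 32. The second component (4.18%) ordered days 20, 25 and 32, and the third (2.02%) ordered days 3, 4 and 5. Libraries of the same day correlated at 0.992 to 0.994 across genes, and those of different days at 0.838 to 0.992; genes are not independent replicates. The share of reads that fell in no gene was 15.9% ± 0.749 at day 3, 17.2% ± 0.455 at day 4, 18.3% ± 0.655 at day 5 and 17.1% ± 1.05 at day 20. It was lower at day 25 (13.8% ± 0.130) and day 32 (12.8% ± 0.608). The quasi-likelihood F test over all 6 days called 19523 of 21283 genes (91.7%) at an adjusted p under 0.05.

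**Figure D1:**
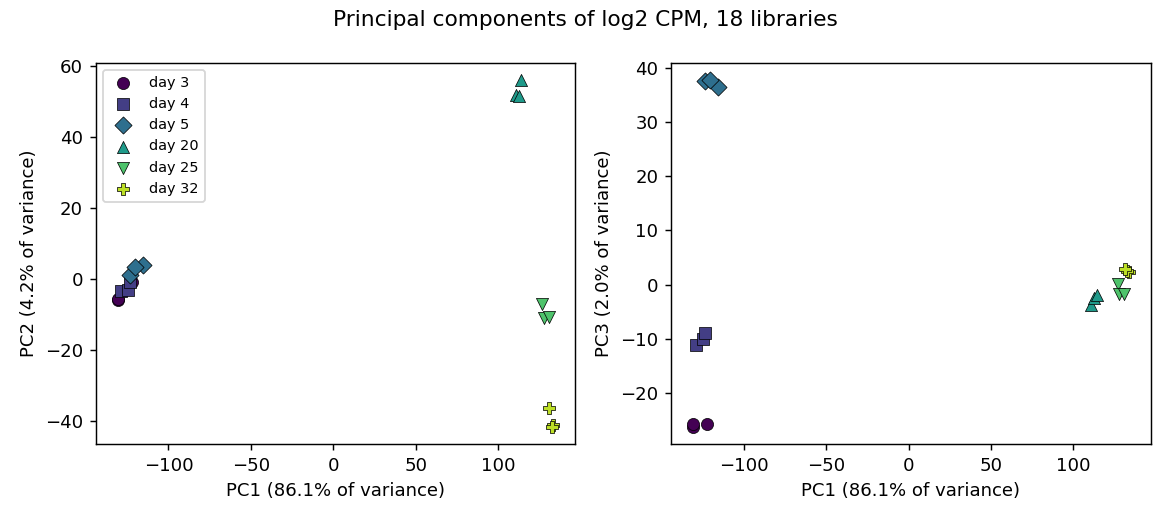
Principal components of log2 CPM for the 18 libraries, with PC1 on both horizontal axes, PC2 (left) and PC3 (right) on the vertical axes, and 1 point per library, coloured and shaped by day. Days 3 to 5 lie apart from days 20 to 32 along PC1 (86.1% of the variance).

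The marker genes were fixed before the data were examined. POU5F1, a core pluripotency factor (ENSG00000204531, chromosome 6, 31164337 to 31180731), was at 758 ± 109.9 CPM at day 3, 737 ± 44.9 at day 4, 505 ± 37.7 at day 5 and 0.153 ± 0.0654 at day 20. NANOG, another such factor, was at 116 ± 7.83 CPM at day 3, 11.2 ± 0.578 at day 5 and 0.0884 ± 0.0159 at day 20. SOX2, which both pluripotent and neural progenitor cells express, was at 266 ± 19.4 CPM at day 3, 318 ± 11.3 at day 5, 369 ± 18.1 at day 20 and 277 ± 13.1 at day 32. PAX6, a transcription factor of neural progenitors, was at 9.83 ± 3.69 CPM at day 5 and 173 ± 2.87 at day 20. HES5, a Notch target of neural progenitors, was at 4.51 ± 2.09 CPM at day 5, 226 ± 8.71 at day 20 and 134 ± 10.003 at day 32. EMX2, a dorsal forebrain factor, stood at 43.2 ± 16.3 CPM at day 20 and 34.9 ± 4.20 at day 32. The markers of cortical intermediate progenitors and deep-layer neurons had low levels, with EOMES at 3.19 ± 0.680 CPM and TBR1 at 9.46 ± 0.782 CPM at day 32. DCX, a microtubule protein of young neurons, went from 17.9 ± 2.02 CPM at day 5 to 1374 ± 57.0 at day 25. TTR, the main secreted protein of choroid plexus, had 0 counts at days 3 and 4 and was at 4.75 ± 4.51 CPM at day 32, where its SD was close to its mean. MKI67, a proliferation marker, was at 538 ± 8.60 CPM at day 5 and 400.3 ± 50.3 at day 32.

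**Figure D2:**
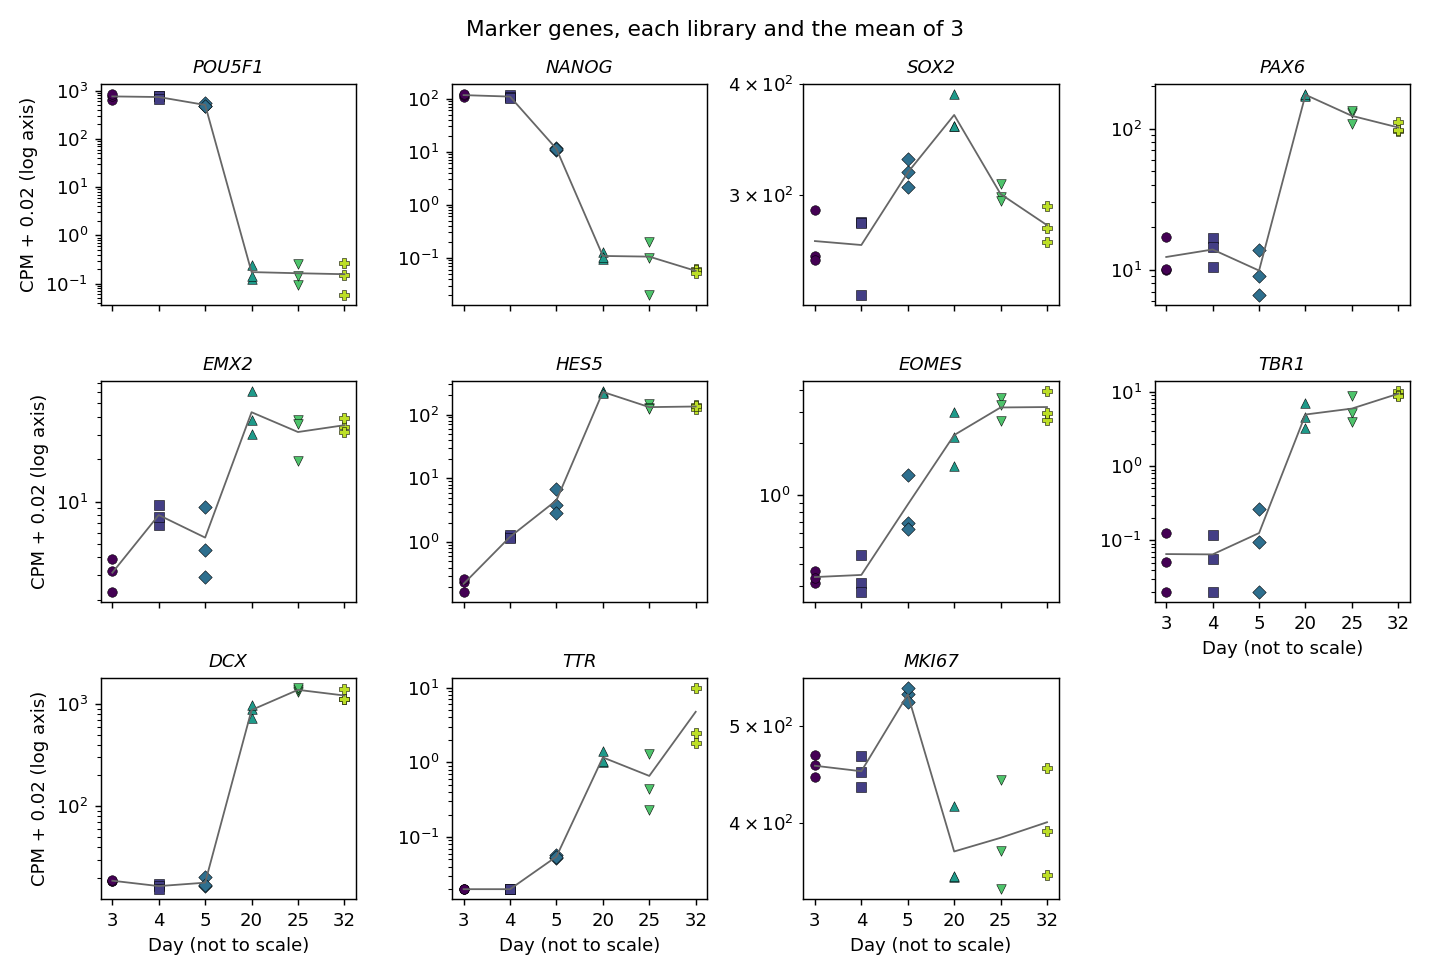
Level of marker genes by day, as CPM plus 0.02 on a log axis, with 1 point per library and a line through the mean of the 3 libraries of a day; the days are spaced evenly, not to scale. POU5F1 fell from 505 ± 37.7 CPM at day 5 to 0.153 ± 0.0654 at day 20, and DCX rose from 17.9 ± 2.02 to 873 ± 129 CPM.

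From day 3 to day 4 the early neural plate genes SOX1 and HES5 rose from low levels, and the list of blood vessel and blood cell markers was called down. SOX1, a transcription factor of the early neural plate, rose from 0.474 ± 0.114 to 3.56 ± 0.671 CPM (log2 fold change 2.90, SE 0.39, adjusted p = 7.97e-04). HES5, a Notch target, rose from 0.203 ± 0.0507 to 1.19 ± 0.0687 CPM (log2 fold change 2.52, SE 0.61, adjusted p = 0.0329). The HES5 call was lost when any 1 of the 6 libraries was left out (adjusted p 0.0845 to 0.1003). The largest rises under the naming rule were in NOS2 (from 3.02 ± 0.664 to 9.86 ± 1.61 CPM) and MMRN1 (from 1.81 ± 0.942 to 5.90 ± 1.02 CPM). IGFBP5 rose from 19.2 ± 8.82 to 57.1 ± 18.2 CPM and the Notch ligand gene DLL1 from 2.35 ± 0.354 to 6.25 ± 1.20 CPM. The neural POU factor gene POU3F4 rose from 3.03 ± 0.762 to 6.65 ± 0.495 CPM. The largest falls under that rule, which asks for at least 5 CPM in the higher day, were in GCNT4 (from 16.4 ± 4.75 to 6.20 ± 1.37 CPM) and STMN2 (from 7.38 ± 0.606 to 3.10 ± 0.742 CPM). The von Willebrand factor gene VWF fell from 9.23 ± 2.11 to 3.98 ± 0.763 CPM. PKDCC fell from 76.8 ± 16.9 to 35.1 ± 4.34 CPM and SEMA6D from 66.0 ± 19.8 to 30.8 ± 8.31 CPM. The call for MMRN1 was lost without day 3 replicate 2, day 3 replicate 4, day 4 replicate 2, day 4 replicate 3 or day 4 replicate 4 (adjusted p 0.0580 to 0.0988). The call for SEMA6D was lost without day 3 replicate 1, day 3 replicate 4, day 4 replicate 2 or day 4 replicate 3 (adjusted p 0.0601 to 0.0938). That for IGFBP5 was lost without day 3 replicate 4, day 4 replicate 3 or day 4 replicate 4 (adjusted p 0.0566 to 0.0680).

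Among the fixed lists, the blood vessel and blood cell markers fell from day 3 to day 4 (adjusted p = 2.05e-04). Of 8 tested members 0 rose, 3 fell and 5 did not pass (1 and 3 adjusted over the list alone). Besides VWF, the endothelial cadherin gene CDH5 fell from 3.36 ± 1.08 to 1.12 ± 0.137 CPM (log2 fold change -1.58, SE 0.26, adjusted p = 3.54e-04) and TIE1 from 7.97 ± 1.42 to 4.50 ± 1.12 CPM. This was the 1 list of the step whose call held with an estimated correlation (adjusted p = 0.0167). The BMP response list fell (adjusted p = 0.00197, and adjusted p = 0.420 with an estimated correlation). Of its 12 tested members 0 rose, 1 fell and 11 did not pass (0 and 5 adjusted over the list alone). The member that fell was SMAD7, an inhibitor that the pathway induces (from 32.3 ± 3.22 to 19.7 ± 1.21 CPM). The neural crest list fell (adjusted p = 0.0154, and adjusted p = 0.195 with an estimated correlation). Of its 10 tested members 0 rose, 1 fell and 9 did not pass (0 and 2 adjusted over the list alone). The neurotrophin receptor gene NGFR fell from 18.4 ± 2.77 to 9.02 ± 0.392 CPM (log2 fold change -1.03, SE 0.11, adjusted p = 2.92e-06). The neural crest call was lost without day 3 replicate 1 (adjusted p = 0.0541) or day 4 replicate 2 (adjusted p = 0.0503).

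The p53 targets, the dorsal forebrain factors and the early neural plate list were called up from day 3 to day 4. In these lists 1, 1 and 2 members rose, namely BAX, NR2F1, and SOX1 with HES5. The lists had an adjusted p = 2.22e-04, an adjusted p = 0.00627 and an adjusted p = 0.0231. With an estimated correlation the adjusted p was 0.195, 0.420 and 0.497. With fry the dorsal forebrain and neural plate calls were lost (adjusted p = 0.0765 and 0.150). Adjusted over the list alone, 3, 1 and 3 members rose. The median log2 fold change of the neural plate list was -0.01 against a mean of 0.37. The neural plate call was lost without day 3 replicate 2 (adjusted p = 0.359) or replicate 4 (adjusted p = 0.0546). It was also lost without day 4 replicate 3 (adjusted p = 0.104) or replicate 4 (adjusted p = 0.0824). The dorsal forebrain call was lost without day 3 replicate 4 (adjusted p = 0.0757). BAX, a mediator of apoptosis, rose from 58.1 ± 3.53 to 66.7 ± 0.904 CPM and NR2F1 from 0.825 ± 0.118 to 1.80 ± 0.242 CPM. The BAX call was lost without day 3 replicate 1, day 3 replicate 2, day 4 replicate 2, day 4 replicate 3 or day 4 replicate 4 (adjusted p 0.0601 to 0.200). The HES5 call was lost without any 1 of the 6 libraries (adjusted p 0.0845 to 0.1003).

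From day 3 to day 4, 981 of 21283 genes passed, 337 up and 644 down (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 87 had an estimated change of at least 2-fold, 48 up and 39 down. In the test against a 2-fold change 0 genes passed (91 at an unadjusted p under 0.05). Without a minimum fold the estimated counts gave 973 genes, with 451 up and 522 down. Without genes that differ over 2-fold between the tables, a fit chosen after seeing the data, 987 passed, 444 up and 543 down. The count was 530, 564 and 470 without day 4 replicate 2, 3 and 4, and 527 when the fit held only the 6 libraries of these days. When only the 6 libraries of these days were tested, 3 of their 10 splits into 3 and 3, the real one included, gave as many list calls as the days did (6, highest other 12).

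Between day 4 and day 5 the NODAL, BMP and pluripotency lists were called down and the integrated and ER stress list up, at the preset correlation. NANOG, a core pluripotency factor (ENSG00000111704, chromosome 12, 7787794 to 7799141), fell from 109 ± 8.64 to 11.2 ± 0.578 CPM (log2 fold change -3.27, SE 0.08, adjusted p = 1.42e-22). NANOGP8, a near-identical copy whose reads cannot be told apart from NANOG with certainty, fell from 19.0 ± 0.957 to 2.07 ± 0.334 CPM. POU5F1 fell from 737 ± 44.9 to 505 ± 37.7 CPM (log2 fold change -0.55, SE 0.09, adjusted p = 3.39e-04). The pluripotency list fell (adjusted p = 5.34e-18, and adjusted p = 0.00668 with an estimated correlation). Of its 14 tested members 0 rose, 9 fell and 5 did not pass (1 and 9 adjusted over the list alone). PRDM14 fell from 59.9 ± 3.04 to 23.2 ± 0.889 CPM and the DNA methyltransferase gene DNMT3B from 1698 ± 65.8 to 1288 ± 33.2 CPM. The NODAL and activin response list fell (adjusted p = 1.06e-12, and adjusted p = 5.70e-04 with an estimated correlation). Of its 10 tested members 0 rose, 6 fell and 4 did not pass (0 and 6 adjusted over the list alone). LEFTY1, a feedback inhibitor of NODAL, fell from 3.54 ± 0.566 to 0.0669 ± 0.0538 CPM (log2 fold change -5.60, SE 0.35, adjusted p = 1.62e-12). LEFTY2 fell from 3.35 ± 0.683 to 0.195 ± 0.0279 CPM and NODAL itself from 4.21 ± 0.284 to 1.40 ± 0.123 CPM. The level of NODAL is uncertain, with 1142 counts against 362 estimated counts over all libraries.

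The BMP response list also fell from day 4 to day 5 (adjusted p = 1.06e-12, and adjusted p = 0.0521 with an estimated correlation). Of its 12 tested members 0 rose, 5 fell and 7 did not pass (1 and 5 adjusted over the list alone). SMAD7 fell from 19.7 ± 1.21 to 2.53 ± 0.636 CPM (log2 fold change -2.95, SE 0.14, adjusted p = 3.35e-15) and the pseudoreceptor gene BAMBI from 16.2 ± 1.13 to 3.98 ± 0.233 CPM. ID1, a direct BMP target and 1 of the 5 largest falls under the naming rule, fell from 29.3 ± 2.93 to 2.93 ± 0.274 CPM (log2 fold change -3.32, SE 0.43, adjusted p = 1.63e-04). The WNT response list fell (adjusted p = 3.58e-04, and adjusted p = 0.118 with an estimated correlation). Of its 11 tested members 0 rose, 4 fell and 7 did not pass (1 and 6 adjusted over the list alone). SP5 fell from 1.91 ± 0.401 to 0.306 ± 0.206 CPM and NKD1 from 24.8 ± 0.824 to 15.8 ± 0.899 CPM. The WNT enhancer gene RSPO3 fell from 11.8 ± 3.71 to 1.06 ± 0.459 CPM (log2 fold change -3.45, SE 0.48, adjusted p = 2.68e-04). The mesenchyme list fell (adjusted p = 0.0105, and adjusted p = 0.0936 with an estimated correlation). Of its 10 tested members 0 rose, 3 fell and 7 did not pass (0 and 3 adjusted over the list alone), and PDGFRA fell from 7.27 ± 0.919 to 2.16 ± 0.403 CPM. The integrated and ER stress list rose (adjusted p = 1.07e-09, and adjusted p = 0.144 with an estimated correlation). Of its 12 tested members 7 rose, 0 fell and 5 did not pass (8 and 0 adjusted over the list alone). The mTOR inhibitor gene DDIT4 rose from 14.7 ± 2.36 to 64.0 ± 10.6 CPM (log2 fold change 2.13, SE 0.13, adjusted p = 8.26e-09). The serine synthesis enzyme gene PSAT1 rose from 339 ± 13.6 to 559.6 ± 20.5 CPM and SESN2 from 21.4 ± 0.598 to 41.9 ± 1.45 CPM. ASNS also rose (adjusted p = 5.18e-04), but its level is uncertain, with 982 counts against 73652 estimated counts.

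The hedgehog response list rose from day 4 to day 5 (adjusted p = 0.0105, and adjusted p = 0.385 with an estimated correlation). Of its 9 tested members 3 rose, 1 fell and 5 did not pass (4 and 1 adjusted over the list alone). FOXA2, a transcription factor of floor plate and endoderm, rose from 0.891 ± 0.143 to 9.55 ± 2.196 CPM (log2 fold change 3.41, SE 0.30, adjusted p = 9.81e-08) and the receptor gene PTCH1 from 35.2 ± 0.932 to 60.5 ± 5.28 CPM. Other large rises under the naming rule were in CUZD1 (from 15.6 ± 1.60 to 194 ± 23.7 CPM) and GALNT9 (from 1.02 ± 0.146 to 12.1 ± 0.420 CPM). The adrenergic receptor gene ADRA2A rose from 2.02 ± 0.0562 to 20.7 ± 4.03 CPM and GPRC5A from 0.642 ± 0.205 to 5.75 ± 1.93 CPM. LRR1 (ENSG00000165501, chromosome 14, 49598697 to 49614672) had the largest fitted fall among genes that the naming rule takes at 5 CPM or more (log2 fold change -3.69, SE 1.06, adjusted p = 0.0333). In day 4 replicate 2 it had 25205 counts, and in no other library over 866. Without that library its log2 fold change was -0.18 (adjusted p = 0.270). The LRR1 call was lost without day 4 replicate 2, day 5 replicate 1, day 5 replicate 2 or day 5 replicate 4 (adjusted p 0.1005 to 0.270). Without day 5 replicate 1, 2 or 4 the log2 fold change was -3.70 (adjusted p = 0.103), -3.68 (adjusted p = 0.1005) and -3.70 (adjusted p = 0.102). Without day 4 replicate 3 or 4 it was -4.24 (adjusted p = 0.00895) and -4.24 (adjusted p = 0.00891). From day 4 to day 5, 3400 of 21283 genes passed, 1763 up and 1637 down, and 477 of these had an estimated change of at least 2-fold, 270 up and 207 down. In the test against a 2-fold change 92 genes passed. When only the 6 libraries of these days were tested, 2 of their 10 splits into 3 and 3, the real one included, gave as many list calls as the days did (9, highest other 10).

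From day 5 to day 20, the longest interval, the pluripotency and epithelial lists were called down and the neuronal and the midbrain and hindbrain lists up, at the preset correlation. All 14 tested members of the pluripotency list fell, 14 adjusted over the list alone (list adjusted p = 2.39e-33, and adjusted p = 6.63e-04 with an estimated correlation). L1TD1 fell from 1102 ± 43.1 to 0.149 ± 0.0648 CPM (log2 fold change -12.78, SE 0.13, adjusted p = 4.22e-33). ZFP42 fell from 126 ± 2.37 to 0.0640 ± 0.0233 CPM and DNMT3B from 1288 ± 33.2 to 58.9 ± 2.79 CPM. TDGF1, the NODAL co-receptor gene (ENSG00000241186, chromosome 3, 46574534 to 46582463), had no counts at day 20. It was at least 8008-fold lower than at day 5, against a floor of 3 counts over the 3 libraries. On the same floor CUZD1 was at least 5053-fold lower and CDCP1 at least 1079.6-fold lower. The stem cell transcript ESRG had 1 count over the day 20 libraries, a ratio of 40881 (95% interval 7337 to 1614740.0). The surface ectoderm and epithelium list fell (adjusted p = 6.07e-11, and adjusted p = 0.00359 with an estimated correlation). Of the 9 tested members 2 rose, 7 fell and 0 did not pass (2 and 7 adjusted over the list alone). The epithelial adhesion gene EPCAM fell from 152 ± 3.64 to 0.652 ± 0.151 CPM and CDH1 from 374 ± 48.3 to 0.166 ± 0.0479 CPM. The members TP63, KRT5 and KRT14 were not tested. No test told the fall of this list apart from that of the pluripotency list.

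Neuronal genes rose over the same interval. The pan-neuronal list rose (adjusted p = 1.13e-30, and adjusted p = 0.00967 with an estimated correlation). Of the 16 tested members 15 rose, 1 fell and 0 did not pass (15 and 1 adjusted over the list alone). The RNA-binding protein gene ELAVL4 rose from 0.432 ± 0.108 to 174 ± 13.8 CPM (log2 fold change 8.63, SE 0.12, adjusted p = 5.51e-30). The neurofilament gene NEFL rose from 38.1 ± 2.91 to 408 ± 40.1 CPM and the tau gene MAPT from 3.89 ± 0.0916 to 91.4 ± 10.8 CPM. DCX rose from 17.9 ± 2.02 to 873 ± 129 CPM. The list of intermediate progenitors and neurogenic factors rose (adjusted p = 1.93e-16, and adjusted p = 5.70e-04 with an estimated correlation). Of the 13 tested members 12 rose, 1 fell and 0 did not pass (12 and 1 adjusted over the list alone). INSM1 rose from 0.748 ± 0.113 to 107 ± 7.69 CPM (log2 fold change 7.15, SE 0.13, adjusted p = 4.04e-27). The proneural factor gene NEUROG2 had 3 counts over the day 5 libraries. Its day 20 to day 5 ratio was 758 (95% interval 259 to 3678). Genes of Cajal-Retzius cells, early-born neurons of the cortical surface, rose (adjusted p = 3.24e-11, and adjusted p = 0.00359 with an estimated correlation). Of the 10 tested members 9 rose, 0 fell and 1 did not pass (9 and 0 adjusted over the list alone). EBF3 rose from 0.639 ± 0.182 to 121 ± 13.4 CPM and RELN from 1.72 ± 0.197 to 15.7 ± 1.87 CPM.

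The midbrain and hindbrain list rose at day 20 (adjusted p = 0.00392, and adjusted p = 0.118 with an estimated correlation). Of the 12 tested members 9 rose, 1 fell and 2 did not pass (9 and 1 adjusted over the list alone). HOXA2, a homeobox gene of the hindbrain, had 1 count over the day 5 libraries and reached 31.4 ± 1.54 CPM at day 20. EN2, a gene of the border of midbrain and hindbrain, had 1 count and reached 27.4 ± 1.81 CPM. Their ratios were 2731 (95% interval 489.7 to 107921) and 2369.8 (95% interval 425 to 93645). HOTAIRM1, a transcript of the HOXA cluster (ENSG00000233429, chromosome 7, 27095647 to 27100265), was at least 509.9-fold higher at day 20 than at day 5. Its level is uncertain because it lies antisense in that cluster and the strand setting is not given in the sources used here. The neuropeptide gene ADCYAP1 was at least 831-fold higher, GSX1 at least 484-fold and KLHL1 at least 466-fold. Such bounds and intervals cover counting error only.

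Other regional and progenitor lists were called up at day 20 at the preset correlation. For the dorsal forebrain factors (adjusted p = 0.00109) 9 rose, 1 fell and 3 did not pass (9 and 1 adjusted over the list alone). NR2F1 rose from 1.13 ± 0.188 to 505 ± 21.9 CPM and NR2F2 from 3.55 ± 0.855 to 424 ± 29.6 CPM. TFAP2C fell from 7.20 ± 0.716 to 1.80 ± 0.155 CPM. In the radial glia list (adjusted p = 0.0108) 12 rose, 1 fell and 2 did not pass (13 and 1 adjusted over the list alone). NES rose from 595 ± 28.6 to 1514 ± 23.4 CPM and TTYH1 from 27.4 ± 5.90 to 218 ± 4.24 CPM. In the cortical hem and choroid plexus list (adjusted p = 0.0219) 10 rose, 1 fell and 2 did not pass (10 and 1 adjusted over the list alone). LMX1A, a roof plate factor, rose from 0.233 ± 0.196 to 19.5 ± 2.05 CPM. Among cortical excitatory neuron genes (adjusted p = 0.0290) 8 rose, 2 fell and 3 did not pass (8 and 2 adjusted over the list alone). The glutamate transporter gene SLC17A6 rose from 0.0922 ± 0.0395 to 37.1 ± 3.70 CPM. Among ventral forebrain and interneuron genes (adjusted p = 0.00849) 6 rose, 1 fell and 0 did not pass (6 and 1 adjusted over the list alone). Only 7 of the 13 members of that list were tested, and NKX2-1, DLX1, DLX5, DLX6, LHX8 and ISL1 were not. GAD1, which makes the transmitter GABA, rose from 1.502 ± 0.253 to 10.4 ± 1.54 CPM, while LHX6 fell from 0.692 ± 0.0730 to 0.0652 ± 0.0625 CPM. With an estimated correlation the adjusted p of these 5 lists was 0.362, 0.447, 0.456, 0.325 and 0.118 in that order.

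Signalling and cell cycle lists moved in both directions from day 5 to day 20. Among WNT response genes (adjusted p = 4.89e-05, up) 11 rose, 0 fell and 0 did not pass (11 and 0 adjusted over the list alone). NKD1 rose from 15.8 ± 0.899 to 96.8 ± 4.99 CPM and LGR5 from 0.837 ± 0.364 to 33.2 ± 2.14 CPM. Among Notch response genes (adjusted p = 4.28e-05, up) 11 rose, 1 fell and 0 did not pass (11 and 1 adjusted over the list alone). DLL3 rose from 5.58 ± 1.02 to 53.9 ± 4.39 CPM and HEYL from 3.88 ± 0.853 to 18.8 ± 1.57 CPM. Among BMP response genes (adjusted p = 0.0173, up) 9 rose, 2 fell and 1 did not pass (9 and 2 adjusted over the list alone), and MSX1 rose from 0.284 ± 0.0659 to 24.2 ± 3.16 CPM. Among immediate early genes (adjusted p = 0.00903, up) 9 rose, 1 fell and 0 did not pass (9 and 1 adjusted over the list alone), and DUSP1 rose from 9.55 ± 0.446 to 43.6 ± 3.20 CPM. With an estimated correlation the adjusted p of these 4 was 0.0992, 0.0992, 0.497 and 0.369. Among mitosis genes (adjusted p = 9.09e-04, down) 0 rose, 13 fell and 1 did not pass (0 and 13 adjusted over the list alone). BUB1 fell from 346 ± 27.8 to 95.2 ± 4.99 CPM. Among DNA replication genes (adjusted p = 3.19e-05, down) 1 rose, 13 fell and 0 did not pass (1 and 13 adjusted over the list alone). MCM3 fell from 485 ± 16.99 to 127 ± 14.4 CPM. Among hypoxia and glycolysis genes (adjusted p = 0.0146, down) 5 rose, 9 fell and 2 did not pass (5 and 9 adjusted over the list alone). ADM fell from 46.3 ± 1.95 to 1.23 ± 0.281 CPM. Among blood vessel markers (adjusted p = 0.0168, down) 2 rose, 5 fell and 1 did not pass (2 and 5 adjusted over the list alone). KDR fell from 156 ± 11.8 to 0.702 ± 0.328 CPM. Among NODAL and activin response genes (adjusted p = 0.0426, down) 2 rose, 5 fell and 3 did not pass (2 and 5 adjusted over the list alone). FOXH1 fell from 25.7 ± 2.70 to 0.0522 ± 0.0268 CPM. For these 5 falls the adjusted p with an estimated correlation was 0.385, 0.420, 0.420, 0.109 and 0.148. The NODAL call was lost without day 20 replicate 3 (adjusted p = 0.0533) and with DESeq2 size factors (adjusted p = 0.0523).

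At no step were 4 of the lists called at the preset correlation. At day 20, of the endoderm genes (6 of 10 tested, adjusted p = 0.478) 1 rose, 5 fell and 0 did not pass (1 and 5 adjusted over the list alone). Of the mesoderm genes (4 of 10 tested, adjusted p = 0.880) 1 rose, 3 fell and 0 did not pass (1 and 3 adjusted over the list alone). Of the retina and pigment epithelium genes (8 of 11 tested, adjusted p = 0.942) 4 rose, 3 fell and 1 did not pass (4 and 3 adjusted over the list alone). Of the astrocyte and oligodendrocyte genes (adjusted p = 0.481) 3 rose, 6 fell and 3 did not pass (3 and 6 adjusted over the list alone). Fry called the endoderm, mesoderm and astrocyte lists down at day 20 (adjusted p = 3.45e-07, 0.0146 and 3.76e-05). It called the retina list down at day 25 (adjusted p = 2.45e-04). From day 5 to day 20, 16385 of 21283 genes passed, 8328 up and 8057 down, and 8449 of these had an estimated change of at least 2-fold, 4451 up and 3998 down. In the test against a 2-fold change 6322 genes passed.

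**Figure D3:**
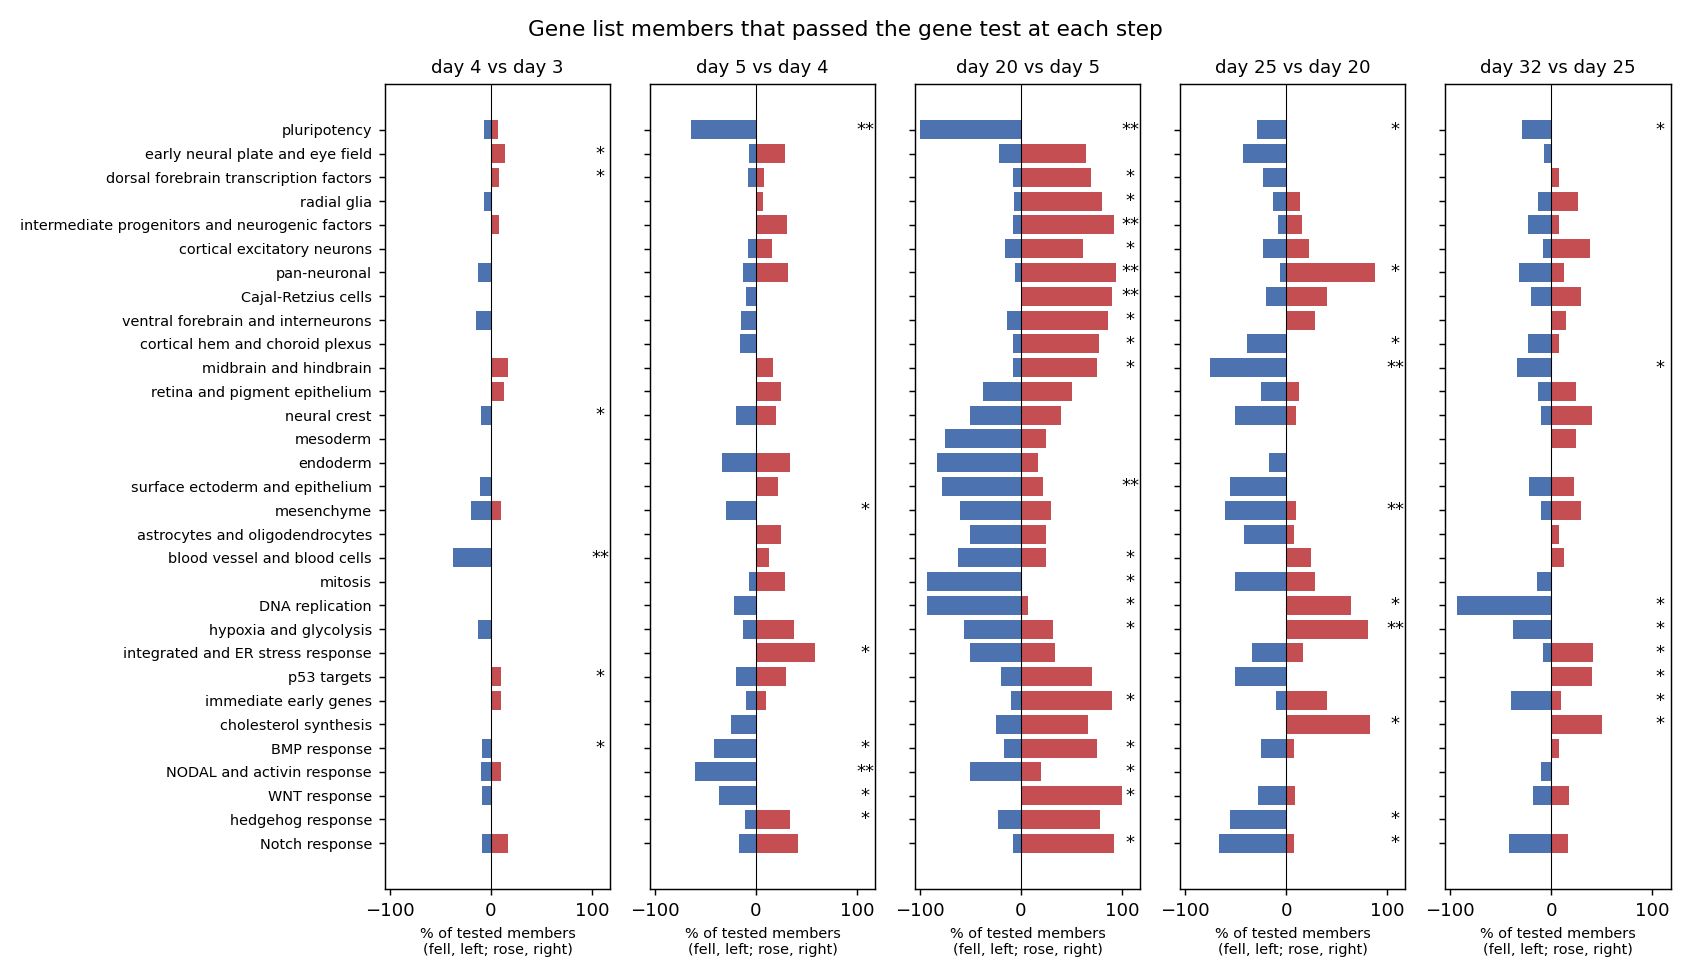
Share of tested members of each fixed gene list that rose (red, right) or fell (blue, left) at each of the 5 steps, in percent of the tested members; 1 star marks lists called by the preset-correlation test and 2 stars those also called with an estimated correlation. The pluripotency list fell in all 14 tested members from day 5 to day 20.

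From day 20 to day 25 the glycolysis, neuronal and cholesterol synthesis lists were called up and the midbrain and hindbrain and mesenchyme lists down, at the preset correlation. The hypoxia and glycolysis list rose (adjusted p = 8.97e-21, and adjusted p = 0.00359 with an estimated correlation). Among its 16 tested members 13 rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone). The kinase gene PDK1, which limits pyruvate oxidation, rose from 26.1 ± 3.46 to 96.6 ± 3.57 CPM (log2 fold change 1.89, SE 0.08, adjusted p = 1.32e-16). The hexokinase gene HK2 rose from 46.0 ± 5.75 to 161 ± 4.65 CPM, PGK1 from 225 ± 19.2 to 493 ± 7.82 CPM and ENO1 from 677 ± 16.7 to 1213 ± 40.7 CPM. The pan-neuronal list rose (adjusted p = 1.90e-11, and adjusted p = 0.0857 with an estimated correlation). Among its 16 tested members 14 rose, 1 fell and 1 did not pass (14 and 1 adjusted over the list alone). NEFL rose from 408 ± 40.1 to 743 ± 2.45 CPM and the synaptic vesicle gene SYP from 27.7 ± 1.73 to 48.5 ± 2.39 CPM. The cholesterol synthesis list rose (adjusted p = 1.90e-11, and adjusted p = 0.110 with an estimated correlation). Among its 12 tested members 10 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone). SQLE, which encodes squalene epoxidase, rose from 198 ± 10.4 to 342 ± 12.3 CPM (log2 fold change 0.79, SE 0.06, adjusted p = 8.67e-11). The DNA replication list rose (adjusted p = 2.46e-04, and adjusted p = 0.473 with an estimated correlation). Among its 14 tested members 9 rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone), and RRM2 rose from 109 ± 8.10 to 203 ± 19.0 CPM. Between the same days the share of reads in no gene went from 17.1% ± 1.05 to 13.8% ± 0.130. The share of counts in histone genes went from 1.10% ± 0.0984 to 1.64% ± 0.0755.

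The midbrain and hindbrain list fell from day 20 to day 25 (adjusted p = 2.43e-05, and adjusted p = 0.0334 with an estimated correlation). Among its 12 tested members 0 rose, 9 fell and 3 did not pass (0 and 9 adjusted over the list alone). EN2 fell from 27.4 ± 1.81 to 8.35 ± 1.87 CPM (log2 fold change -1.72, SE 0.13, adjusted p = 8.54e-11) and HOXA2 from 31.4 ± 1.54 to 20.3 ± 1.24 CPM. PAX8, 1 of the 5 largest falls under the naming rule, fell from 9.01 ± 1.41 to 0.456 ± 0.0860 CPM (log2 fold change -4.30, SE 0.58, adjusted p = 6.39e-05). The mesenchyme list fell (adjusted p = 0.00102, and adjusted p = 0.0334 with an estimated correlation). Among its 10 tested members 1 rose, 6 fell and 3 did not pass (1 and 6 adjusted over the list alone). The collagen genes COL1A2 and COL3A1 fell from 88.0 ± 8.33 to 26.4 ± 3.81 CPM and from 24.1 ± 5.62 to 6.68 ± 2.30 CPM. The Notch response list fell (adjusted p = 0.00173, and adjusted p = 0.196 with an estimated correlation). Among its 12 tested members 1 rose, 8 fell and 3 did not pass (1 and 8 adjusted over the list alone), and LFNG fell from 83.7 ± 2.47 to 46.2 ± 1.45 CPM. The pluripotency list fell (adjusted p = 5.65e-04, and adjusted p = 0.240 with an estimated correlation). Among its 14 tested members 0 rose, 4 fell and 10 did not pass (0 and 4 adjusted over the list alone). LIN28A, which early neural progenitors also express, fell from 152 ± 16.7 to 43.0 ± 4.85 CPM and SALL4 from 168 ± 7.61 to 66.6 ± 16.3 CPM. The hedgehog response list fell (adjusted p = 0.0363, and adjusted p = 0.442 with an estimated correlation). Among its 9 tested members 0 rose, 5 fell and 4 did not pass (0 and 5 adjusted over the list alone), and GAS1 fell from 102 ± 5.40 to 61.9 ± 2.74 CPM. This call was lost without day 20 replicate 3 (adjusted p = 0.0676) or day 25 replicate 2 (adjusted p = 0.0879), and in the estimated counts (adjusted p = 0.0575). The cortical hem and choroid plexus list fell (adjusted p = 0.0281, and adjusted p = 0.457 with an estimated correlation). Among its 13 tested members 0 rose, 5 fell and 8 did not pass (0 and 5 adjusted over the list alone), and CLIC6 fell from 4.02 ± 0.937 to 0.506 ± 0.176 CPM. The hem call was lost without day 25 replicate 4 (adjusted p = 0.0637).

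Among genes at 5 CPM or more in the higher day, as the naming rule asks, the largest rises at day 25 were led by the transporter gene SLC16A6, from 0.587 ± 0.221 to 14.4 ± 1.37 CPM (log2 fold change 4.58, SE 0.17, adjusted p = 8.54e-18). The transcriptional repressor gene BHLHE40 rose from 1.16 ± 0.296 to 9.76 ± 0.542 CPM and LUZP2 from 2.80 ± 0.587 to 20.8 ± 3.28 CPM. The neuropeptide precursor gene VGF rose from 2.06 ± 0.415 to 10.02 ± 0.793 CPM and ARRDC3 from 159 ± 2.31 to 723 ± 27.6 CPM. Besides PAX8, the largest falls under that rule were in A2M (from 10.3 ± 1.25 to 2.27 ± 0.330 CPM) and ATP8B3 (from 7.31 ± 0.745 to 1.63 ± 0.380 CPM). NOS2 fell from 22.4 ± 3.40 to 5.09 ± 1.56 CPM and TESMIN from 10.9 ± 0.827 to 2.57 ± 0.525 CPM. From day 20 to day 25, 8241 of 21283 genes passed, 4378 up and 3863 down, and 1358 of these had an estimated change of at least 2-fold, 455 up and 903 down. In the test against a 2-fold change 162 genes passed.

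From day 25 to day 32 the DNA replication, glycolysis and immediate early lists were called down and the stress, p53 and cholesterol synthesis lists up, at the preset correlation. None of the 8 list calls of this step held with an estimated correlation, where 4 lists had an unadjusted p under 0.05. Fry called 17 lists. The DNA replication list fell (adjusted p = 4.03e-09, and adjusted p = 0.267 with an estimated correlation). Of the 14 tested members 0 rose, 13 fell and 1 did not pass (0 and 14 adjusted over the list alone). MCM5 fell from 84.4 ± 4.30 to 60.4 ± 4.19 CPM (log2 fold change -0.48, SE 0.07, adjusted p = 1.47e-05) and RRM2 from 203 ± 19.0 to 151 ± 11.7 CPM. The hypoxia and glycolysis list fell (adjusted p = 4.08e-05, and adjusted p = 0.148 with an estimated correlation). Of the 16 tested members 0 rose, 6 fell and 10 did not pass (0 and 6 adjusted over the list alone). HK2 fell from 161 ± 4.65 to 95.5 ± 7.68 CPM and LDHA from 217 ± 14.6 to 126 ± 7.45 CPM. The immediate early list fell (adjusted p = 4.35e-05, and adjusted p = 0.118 with an estimated correlation). Of the 10 tested members 1 rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone). FOS fell from 36.8 ± 5.13 to 14.1 ± 0.359 CPM and EGR1 from 27.3 ± 0.563 to 10.4 ± 0.908 CPM. The pluripotency list fell (adjusted p = 6.27e-07, and adjusted p = 0.0972 with an estimated correlation). Of the 14 tested members 0 rose, 4 fell and 10 did not pass (0 and 4 adjusted over the list alone). LIN28A, an RNA-binding protein gene (ENSG00000131914, chromosome 1, 26410778 to 26429722), fell from 43.0 ± 4.85 to 8.12 ± 1.502 CPM (log2 fold change -2.40, SE 0.12, adjusted p = 4.47e-11) and DPPA4 from 24.4 ± 2.42 to 8.36 ± 0.499 CPM. The midbrain and hindbrain list fell (adjusted p = 0.00903, and adjusted p = 0.150 with an estimated correlation). Of the 12 tested members 0 rose, 4 fell and 8 did not pass (0 and 5 adjusted over the list alone). HOXA2 fell from 20.3 ± 1.24 to 13.3 ± 2.36 CPM (log2 fold change -0.62, SE 0.11, adjusted p = 1.60e-04).

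The integrated and ER stress list rose from day 25 to day 32 (adjusted p = 5.68e-04, and adjusted p = 0.420 with an estimated correlation). Of the 12 tested members 5 rose, 1 fell and 6 did not pass (5 and 1 adjusted over the list alone). HERPUD1 rose from 43.6 ± 1.40 to 88.1 ± 2.43 CPM (log2 fold change 1.01, SE 0.07, adjusted p = 2.72e-11) and the chaperone gene HSPA5 from 408 ± 14.6 to 564 ± 22.9 CPM. The p53 target list rose (adjusted p = 0.0258, and adjusted p = 0.447 with an estimated correlation). Of the 10 tested members 4 rose, 0 fell and 6 did not pass (4 and 1 adjusted over the list alone). The cell cycle inhibitor gene CDKN1A rose from 53.6 ± 8.91 to 112 ± 5.37 CPM (log2 fold change 1.06, SE 0.08, adjusted p = 1.52e-09). The p53 call was lost without day 25 replicate 4 (adjusted p = 0.0542) or day 32 replicate 3 (adjusted p = 0.0898). The cholesterol synthesis list rose (adjusted p = 0.00523, and adjusted p = 0.497 with an estimated correlation). Of the 12 tested members 6 rose, 0 fell and 6 did not pass (7 and 0 adjusted over the list alone), and MVD rose from 55.9 ± 5.22 to 83.1 ± 0.511 CPM.

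With the same minimum of 5 CPM, the largest rises at day 32 were in ZPLD1 (from 0.497 ± 0.139 to 7.84 ± 0.870 CPM) and the neuronal adhesion gene ICAM5 (from 1.24 ± 0.235 to 17.2 ± 1.45 CPM). PI15 rose from 2.70 ± 0.636 to 13.9 ± 3.06 CPM and SPOCK3 from 4.81 ± 0.765 to 23.1 ± 2.92 CPM. SEMA3E rose from 1.89 ± 0.562 to 9.09 ± 1.13 CPM, with an uncertain level (6065 counts against 2006 estimated counts). Besides LIN28A, the largest falls with that minimum were in MYBPC1 (from 13.9 ± 2.34 to 3.17 ± 0.570 CPM) and the glycine transporter gene SLC6A5 (from 13.6 ± 2.09 to 3.48 ± 0.502 CPM). COL14A1 fell from 17.4 ± 4.74 to 4.92 ± 0.292 CPM and the growth factor gene FGF10 from 5.69 ± 0.726 to 1.63 ± 0.655 CPM. From day 25 to day 32, 4357 of 21283 genes passed, 2316 up and 2041 down, and 491 of these had an estimated change of at least 2-fold, 317 up and 174 down. In the test against a 2-fold change 44 genes passed. When only the 6 libraries of these days were tested, 3 of their 10 splits into 3 and 3, the real one included, gave as many list calls as the days did (8, highest other 10).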

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

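The alternatives were fixed before the data were examined, except the fit without genes that differ between the 2 kinds of counting table. The counts of changed genes at all 5 steps and over the course moved by less than 1.5 times with either table of estimated counts, DESeq2, DESeq2 size factors, no low-count filter, without genes over 1% of a library, and without genes that differ between the tables. With a test against a 2-fold change, 0 genes passed from day 3 to day 4 (91 at an unadjusted p under 0.05; the test without a minimum fold called 981 and DESeq2 1177), and 92, 6322, 162 and 44 at the later steps, because that test asks for a larger change. With only the 6 libraries of the days, 527 genes passed from day 3 to day 4; fewer samples and genes were then tested. Leaving out 1 library gave 470 to 892, 2458 to 2668, 15949 to 16063, 6980 to 7489 and 3250 to 3765 genes at the 5 steps in order, and 19585 to 19836 over the course. The share of calls that were up from day 3 to day 4 was 34.4% in the counts and 46.4% in the estimated counts, and 44.98% without genes that differ between the tables. For lists, an estimated correlation left 1, 2, 5, 3 and 0 calls at the 5 steps (with 6, 7, 20, 10 and 8 at the preset correlation). In some lists whose call was lost, the estimate was far above the preset value. From day 25 to day 32 it was 0.685 for DNA replication, 0.528 for stress and 0.514 for cholesterol synthesis. The preset p-values of such lists assume less shared variation than was estimated. Calls were also lost with estimates under the preset value. This held for the mesenchyme list at day 5 (-0.00627) and the blood vessel (-0.0530) and NODAL (-0.0555) lists at day 20. The cause of those losses was not tested. At the last step, 4 lists had an unadjusted p under 0.05 with the estimated correlation, and fry called 17. Fry, which does not compare a list with other genes, called 4, 12, 30, 20 and 17 lists at the 5 steps, among them 4 of the 6 called at the first. Leaving out 1 library gave 5 to 6, 7 to 11, 19 to 21, 9 to 13 and 7 to 11 lists, the highest at day 5 without day 5 replicate 4. Among 518 results of named genes, 2 changed direction in either table of estimated counts, and the cause was not tested. BEST1, from day 5 to day 20, had a log2 fold change of 0.94 (adjusted p = 2.44e-05) in the counts and -0.17 (adjusted p = 0.271) in the estimated counts. GRHL2, from day 25 to day 32, had -1.24 (adjusted p = 0.0162) and 0.71 (adjusted p = 0.786). Besides these, the named-gene calls lost were 15 in the fractional estimated counts, 6 with DESeq2, where 9 results had no adjusted p and were not counted, 303 with the 2-fold test, 19 with only the libraries of the days, 14 with no low-count filter, 2 without genes that differ between the tables, 2 with DESeq2 size factors and 2 without genes over 1% of a library. Without a library, 281 calls of named genes were lost over all left-out libraries. Depth limits the genes with few counts, where a day without counts gives only a bound.

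The same replicate numbers recur between days, but the labels do not say that a number marks a shared culture. Deviations from the day means of same-numbered libraries of neighbouring days correlated at -0.0419 to 0.136 (median 0.0531, 1 of 10 over 0.1). Those of different-numbered libraries correlated at -0.126 to 0.112 (median -0.0129, 2 of 35 over 0.1). The median was thus higher for equal numbers, and a shared culture stays open. Because the labels name none, the main fit did not take the numbers as pairs. With the replicate number as a block, 871, 3050, 16121, 7846 and 3957 genes passed at the 5 steps and 19352 over the course, and 10 lists were called from day 3 to day 4, while 21 calls of named genes were lost and 5 gained.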

Other observations

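Of the tests in this part, the count comparison for LRR1, the tests of handling at harvest and of normalization, and the test of a library of the wrong stage were chosen only after the result was seen. Some lists that were not called held members that moved, alone or in opposite directions. From day 25 to day 32 the cortical excitatory neuron list was not called (adjusted p = 0.0578), and 5 rose, 1 fell and 7 did not pass (5 and 1 adjusted over the list alone). BCL11B, a transcription factor of deep-layer projection neurons, rose from 6.78 ± 0.520 to 17.002 ± 2.40 CPM (log2 fold change 1.32, SE 0.14, adjusted p = 2.33e-07), NFIB rose from 12.9 ± 0.595 to 33.3 ± 4.83 CPM and NEUROD2 from 0.297 ± 0.147 to 1.36 ± 0.587 CPM, while the glutamate transporter gene SLC17A6 fell from 39.4 ± 4.52 to 28.8 ± 2.001 CPM. In the radial glia list (adjusted p = 0.0908) 4 rose, 2 fell and 9 did not pass (7 and 2 adjusted over the list alone). Among its members LIFR rose from 105 ± 10.7 to 193 ± 6.94 CPM, TNC from 3.58 ± 0.851 to 12.6 ± 2.04 CPM and FAM107A from 3.91 ± 2.17 to 16.9 ± 2.97 CPM, and NES, an intermediate filament gene of neural progenitors, fell from 2151 ± 176 to 1712 ± 203 CPM. From day 20 to day 25, in the Cajal-Retzius list (adjusted p = 0.0536), 4 rose, 2 fell and 4 did not pass (4 and 2 adjusted over the list alone). RELN rose from 15.7 ± 1.87 to 59.8 ± 3.91 CPM (log2 fold change 1.93, SE 0.09, adjusted p = 2.95e-15) and PCP4 from 1.41 ± 0.503 to 4.31 ± 0.575 CPM, while CALB2 fell from 3.69 ± 1.04 to 1.21 ± 0.226 CPM.

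From day 5 to day 20 the neural crest list was not called (adjusted p = 0.134), and 4 rose, 5 fell and 1 did not pass (4 and 5 adjusted over the list alone). TFAP2B rose from 0.206 ± 0.0196 to 127 ± 15.1 CPM (log2 fold change 9.23, SE 0.18, adjusted p = 4.57e-21) and TFAP2A from 0.348 ± 0.201 to 90.9 ± 17.2 CPM, while FOXD3, which pluripotent cells also express, had 1 count over the day 20 libraries and a ratio of day 5 to day 20 of 466 (95% interval 83.3 to 18439). Among the mesenchyme genes (adjusted p = 0.899) COL3A1 rose from 0.0544 ± 0.0668 to 24.1 ± 5.62 CPM and COL6A3 fell from 5.58 ± 0.907 to 0.141 ± 0.0905 CPM. From day 20 to day 25, 4 rose, 7 fell and 3 did not pass (4 and 7 adjusted over the list alone) in the mitosis list (adjusted p = 0.171), and AURKA fell from 42.6 ± 0.592 to 29.4 ± 1.05 CPM and CCNB2 from 90.1 ± 2.80 to 71.1 ± 2.26 CPM.

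The midbrain and hindbrain list rose at day 20, with a median log2 fold change of 4.60 against day 5 (3.75 with members that had no counts on a day at their bound). The planned test for reads of overlapping genes did not come out as predicted for them, since the estimated counts gave a median of 5.24, without such bounds. The rise was thus not particular to 1 kind of counting table. How the estimated counts treat overlapping genes is not given in the sources used here, so such reads are not excluded. The planned test for a mislabelled library came out as predicted for one: the lowest summed CPM of a library of days 20 to 32 was 0.681 times the highest of days 3 to 5. That low sum was shared by the 3 day 32 libraries (38.4 to 43.0 CPM, against 127 to 133 at day 20, 58.9 to 68.5 at day 25 and 23.5 to 56.3 on days 3 to 5), so the written bound wrongly took the level to hold to day 32, and the correlation of a late with an early library was at most 0.869 against at least 0.992 within a day. An unequal share of another culture cannot be told apart from a shared response (median coefficient of variation of the members at day 20 9.79%, against 7.97% for other genes of like level), and no biological explanation was tested.

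LRR1 had 25205 counts in day 4 replicate 2 against 922 estimated counts there, a ratio of 27.3, while the other libraries had ratios of 0.819 to 0.972. A candidate explanation for the fitted fall is therefore reads counted to the gene in 1 library by 1 counting method. The fractional estimated counts gave a log2 fold change of -0.16 (adjusted p = 0.136), and the adjusted p over the alternatives ranged from 0.00891 to 0.926. A separate screen took the 105502 pairs of a gene and a library with at least 1000 counts. It asked for a ratio of the 2 counts, after a small constant was added, over 5 times the median ratio of the gene. The 2 pairs that passed were LRR1 in day 4 replicate 2 and ENSG00000280800 in day 3 replicate 2 (1780 counts against 0 estimated counts). No biological explanation was tested.

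The hypoxia and glycolysis list rose at day 25 with a median log2 fold change of 0.72. The counting table is argued against as the whole cause, since the estimated counts gave a median of 0.82, and a single library as well, since the lowest median without 1 of the 6 libraries was 0.71. Whether the normalization adds to the rise stays open, because the 2 other scalings moved the median of all genes by at most 0.0197 (log2) and so decide nothing. Handling at the harvest cannot be told apart from a change in the organoids, because each day may be 1 harvest; the immediate early list had a median of 0.14. A difference between the days in the organoids themselves stays open, and no biological explanation was tested.

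With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave 527, 4457, 15692, 8382 and 4551 genes at the 5 steps when only the 6 libraries were fitted, and the highest other split gave 0, 0, 0, 0 and 0 (edgeR, with up to 1248 genes at an unadjusted p under 0.05 in those other splits). Each other split mixed both days, so the difference between the days entered the spread and lowered these counts. From day 5 to day 20 the other splits had only 19 to 43 genes at an unadjusted p under 0.05. The 0 counts are therefore no support. For lists the real splits gave 6, 9, 21, 14 and 8 calls, and 3, 2, 1, 1 and 3 of the 10 splits gave as many, with the highest other at 12, 10, 15, 13 and 10. Over the course, 1 of 40 groupings, the real one included, gave as many genes (19523, highest other 11776), the lowest share that 40 groupings can give. The drawn groupings also mixed days, which lowered their counts. The low share therefore argues only against a random assignment of the libraries to the days and lends no support to the size of the count. It does not test the harvest or other differences tied to the day.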
